A study of Mus musculus with 6 samples.

How the data were processed

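Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin. Per the labels' protocols, nuclei came from frozen mouse muscle, and the libraries were made from the quadriceps femoris, the large extensor muscle of the thigh. There were 3 libraries from mice without Prr14 (KO) and 3 from wild-type mice (WT). Library names carry replicate numbers 3, 4 and 8 for WT and 4, 5 and 7 for KO. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples, which may be technical in part. Age, sex and the part of Prr14 that was deleted are not given in the sources used here.

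The submitters' processing notes name Trimmomatic, BWA, MACS2, deepTools, bedtools, DESeq2 1.6.3 and the mouse genome build GRCm38, without the role or order of each tool. The authors deposited 1 common peak list of 75134 peaks with whole-number counts of reads or fragments per peak and library; the counting tool, read shift, duplicate handling and peak merging are not given in the sources used here. Next to these counts stands a normalized signal by the authors, which equals the count divided by 1 factor per library (quotients within a library differed by at most 9.77e-15 in relative terms). The authors' factors were 0.988, 1.02 and 0.984 for WT replicates 3, 4 and 8 and 1.00, 1.04 and 0.977 for KO replicates 4, 5 and 7. Median-ratio factors computed from the same peak counts were 0.985, 1.09 and 0.762 for WT and 0.940, 1.21 and 1.09 for KO, so the authors' factors differ from those the peak counts give. The deposited table also holds the authors' log2 fold change of KO over WT, their p-values raw and adjusted, a score per peak that is the authors' own, the annotated gene, the class of genomic feature and the distance to the transcription start site. Coordinates and gene assignments are those of the deposited table, and gene spans come from a RefSeq gene table of GRCm38.p6. Peaks in satellite, ribosomal, mitochondrial or ampliconic sequence can share reads with near-identical copies, and their values are uncertain.

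The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM factors and the filter filterByExpr at its defaults (minimum count 10, minimum total 15), which left 73896 peaks. TMM factors were 1.01, 0.940 and 1.00 for WT and 1.02, 1.01 and 1.01 for KO. A peak was called changed at a Benjamini-Hochberg adjusted p below 0.05, and adjusted p-values in the text are of this test unless another is named. Levels are counts per 1000000 (CPM) scaled with TMM, given as mean ± SD of 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F value. Total counts in peaks ran from 7608514 to 12061822 per library, and the common biological coefficient of variation was 0.201. Tested on simulated data of 73388 peaks with the real means, library sizes and dispersions, with 40 peaks changed at each size, the procedure recovered 10% of peaks raised 1.5 times, 77.5% of those raised 2 times, 100% of those raised 4 times, 40% of those lowered to 0.5 and 92.5% of those lowered to 0.25 of the level. Of 130 simulated calls, 2 were false. The changed peaks were drawn from those with a mean signal above its 0.25 quantile, so recovery among the weakest peaks was not measured and may be lower. In this simulation, gains of 1.5 times and losses to 0.5 were thus missed more often than found. The real data gave 5177 calls, where the adjusted p cut-off is less strict, so recovery there may differ.

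Gene lists (23) were tested with camera (limma 3.58.1, inter-gene correlation 0.01, two-sided, adjusted over the lists) on 1 promoter peak per gene, the annotated peak nearest the start site within 3 kb. An estimated correlation and fry, which tests whether a list's own peaks move one way on balance, stood beside it. Both were computed with all libraries only, so list calls under other settings rest on the preset correlation. In simulation with peaks drawn independently, 3% of 200 random unchanged lists passed at an unadjusted p of 0.05. This says nothing of lists whose peaks move together. The estimated correlation was 0.668 in the fast fibre list, 0.709 in the sarcomere list and 0.581 in the calcium handling list. Feature classes and chromosomes were tested with Fisher's exact test, two-sided, against the tested peaks that were not called. Measures with 1 value per library were compared with an exact permutation test, two-sided, whose smallest p is 0.1 with 3 against 3. The lists were type I slow fibre, type II fast fibre, sarcomere, MEF2, myogenic and satellite cell, neuromuscular junction, calcium handling, oxidative phosphorylation, fatty acid oxidation, glycolysis, atrophy, mechanotransduction, nuclear envelope, circadian and immediate early genes, and markers of endothelial, smooth muscle, fibro-adipogenic, tenocyte, macrophage, adipocyte, Schwann and erythroid cells. Figures were drawn with matplotlib.

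The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Prr14, Mef2a, Mef2c, Mef2d and the myosin heavy chain genes Myh7, Myh2, Myh1 and Myh4 by promoter peak and by the called peak with the smallest p. It further named the 10 largest called changes in each direction whose libraries lay apart by group and that were annotated to protein-coding genes on assembled chromosomes, 1 peak per gene. From each gene list that passed its test it took the 3 promoter peaks with the smallest p in the list's direction, and from every list at most 3 called promoter peaks. Some genes that the rule selects are not reported here. Other genes named in the text were chosen after their values were seen, and this is stated where they appear. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters and thresholds, the authors' own table, leaving out X, Y and mitochondrial peaks, and leaving out each library in turn. The use of the authors' factors, with and without WT replicate 8, and totals outside the mitochondrial peaks were added after seeing the data. A search for transcription factor motifs and corrections for GC content need the genome sequence and were not run.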

Results

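Accessibility profiles of the quadriceps femoris were compared between 3 Prr14-KO and 3 Prr14-WT mouse libraries over 73896 tested peaks. PRR14 is a nuclear lamina protein that tethers heterochromatin to the nuclear periphery, and the comparison asks how chromatin accessibility in muscle differs without it, with fibre identity and the transcription factor MEF2C named in the series title. Total counts in peaks were 9593992, 11575061 and 7608514 in WT replicates 3, 4 and 8 and 9346968, 12061822 and 10785830 in KO replicates 4, 5 and 7. Spearman correlations of log2 CPM were 0.920 to 0.933 within WT, 0.939 to 0.949 within KO and 0.904 to 0.922 between the groups. The first principal component held 33.5% of the variance and separated the groups (exact permutation p = 0.1, the smallest possible). On the second, WT replicate 4 lay at -87.4 and WT replicate 8 at 73.0, with the other libraries between -33.0 and 34.3. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 4.07 to 7.47).

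The Prr14 gene (ENSMUSG00000030822) held 1 tested peak, over its promoter (chromosome 7, 127470286 to 127472182, GRCm38). It gave 62.0 ± 4.71 CPM in WT and 60.5 ± 9.75 CPM in KO (SD, n = 3 each), a log2 fold change of -0.03 (SE 0.18, adjusted p = 0.961). The deleted part of the gene is not given, so this peak cannot check the genotype labels.

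In the myosin heavy chain cluster on chromosome 11, 7 of 7 tested peaks annotated to Myh4, 2 of 5 to Myh1 and 1 of 5 to Myh2 fell in KO, and 0 rose. All 7 peaks at Myh4 (ENSMUSG00000057003), which encodes the myosin heavy chain of the fastest fibres (type IIb), were lower, with log2 fold changes between -1.36 and -1.04. The Myh4 promoter peak (67235780 to 67238730) fell from 79.2 ± 23.98 to 37.6 ± 4.27 CPM (log2 fold change -1.08, SE 0.18, adjusted p = 3.95e-07, n = 3 each). At Myh1, the type IIx myosin gene, an exonic peak (67203894 to 67205691) fell by 1.47 on the log2 scale (SE 0.20, adjusted p = 4.34e-11), and at Myh2, the type IIa gene, a peak 30179 bases upstream of the start site fell by 0.88 (SE 0.18, adjusted p = 6.73e-05). At Myh1, 1 peak was lower without WT replicate 4, KO replicate 5 or KO replicate 7; at Myh2, 2 were lower without WT replicate 8, and 1 was higher beside 1 lower without WT replicate 4.

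Chosen after their values were seen, 4 intergenic peaks between Myh3 and Myh2 (67104358 to 67121406) also fell, with log2 fold changes from -1.32 to -0.81. So did a peak over the end of Myh4 (-1.24, SE 0.18). Its deposited class is 3' UTR and its annotated gene is Myh8, but it lies outside the RefSeq span of Myh8 (67277124 to 67308634). The nearest upstream peak of Myh2 (67163084 to 67164733) gave 0.48 (SE 0.23, adjusted p = 0.238). The promoter peak of Myh1 had a log2 fold change of -1.23 that did not pass (SE 0.49, adjusted p = 0.125), and no peak within 3 kb of the Myh2 start site was tested. At Myh8, the perinatal myosin gene, the promoter peak gave 0.22 (SE 0.37, adjusted p = 0.855), and at Myh7, the slow myosin gene on chromosome 14, it gave 0.78 (SE 0.40, adjusted p = 0.286). With the authors' library factors in place of TMM, 2 of the 7 Myh4 peaks passed in edgeR, and the Myh4 promoter peak and the upstream Myh2 peak did not (adjusted p = 0.104 and 0.291), with log2 fold changes of -0.91 and -0.70. Of the 7, 3 passed in the table of the authors.

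**Figure D1:**
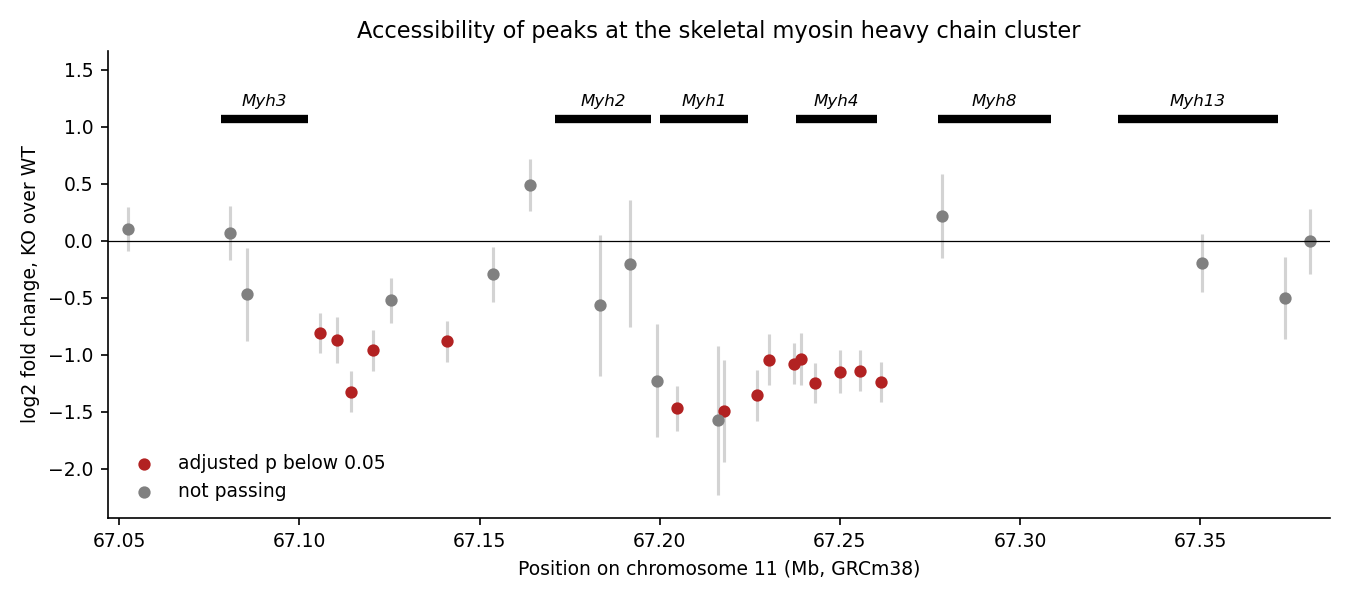
Log2 fold change of KO over WT (vertical axis, bars are the SE) for each tested peak by its position on chromosome 11 in Mb, with gene spans above; red points passed an adjusted p of 0.05 and grey points did not. The called peaks lie from the Myh3 to Myh2 interval through the end of Myh4, all below 0. The Myh8 promoter peak and the Myh13 peaks did not pass.

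Promoters of the type II fast fibre list were lower relative to other promoters by camera with its preset correlation (22 genes, median log2 fold change -0.13, adjusted p = 8.40e-06), but not with an estimated correlation (adjusted p = 0.799). By fry 0 of the 23 lists passed (adjusted p = 0.834 for this list). The list had 0 promoter peaks called higher, 2 called lower (Myh4 and Myl1) and 20 not passing. Adjusted over the list alone, 3 promoter peaks were lower. Myl1, an alkali light chain of fast myosin, fell at its promoter from 30.1 ± 7.58 to 17.1 ± 0.318 CPM (log2 fold change -0.82, SE 0.20, adjusted p = 0.00113). Without WT replicate 4 the median was 0.06 (adjusted p = 0.233). With the authors' factors the median was 0.04, beside a median of 0.19 over all peaks of the authors' table, and camera, which compares the list with other promoters, still passed. Over all peaks of the list's genes, 47 fell and 12 rose among 221, with 7 rising without KO replicate 4 and 5 without KO replicate 5; the authors' table had 22 lower and 7 higher.

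Mylk4, a myosin light chain kinase family gene on the fast fibre list, carried one of the widest losses: 21 of its 28 tested peaks fell and 0 rose. Its largest change was an intronic peak (chromosome 13, 32714629 to 32715276) that fell from 9.94 ± 4.79 to 1.601 ± 0.520 CPM (log2 fold change -2.63, SE 0.31, adjusted p = 3.92e-14). The Mylk4 promoter peak gave -0.55 (SE 0.19, adjusted p = 0.0509) and did not pass; it passed without WT replicate 8 (adjusted p = 0.0170). Between 17 and 22 Mylk4 peaks were lower under the alternatives, the authors' unadjusted p aside, and 0 were higher.

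Slow fibre genes had no common direction. The type I slow fibre list had a median of 0.18 over 16 promoter peaks (camera adjusted p = 0.429), with 2 promoter peaks higher, 0 lower and 14 not passing, and the same counts adjusted over the list alone. Tnnc1, the troponin C gene of slow and cardiac muscle, rose at its promoter from 3.21 ± 0.184 to 7.13 ± 3.11 CPM (log2 fold change 1.14, SE 0.30, adjusted p = 0.00464), a call that was lost without KO replicate 4 (adjusted p = 0.237). Smtnl1, a smoothelin-like gene of muscle, rose by 0.70 (SE 0.18, adjusted p = 0.00341), lost without WT replicate 3 (adjusted p = 0.0777). Over all peaks of these genes the balance was the other way, with 5 higher and 17 lower of 81. Pln, the phospholamban gene, chosen after its counts were seen, held 12 of the lower ones. The lower count was 9 without WT replicate 4 (7 at Pln), 9 without KO replicate 5 (6 at Pln) and 11 without KO replicate 7, and the higher count 8 without WT replicate 4 and 3 without KO replicate 4. The authors' table had 5 higher and 4 lower.

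Promoters of shared sarcomere genes were lower by camera with its preset correlation (19 genes, median -0.13, adjusted p = 0.00193), but not with an estimated correlation (adjusted p = 0.799) or by fry (adjusted p = 0.834). Of these promoters 1 was higher, 2 were lower and 16 did not pass, also when adjusted over the list alone. The promoter of Klhl41, a gene needed for sarcomere integrity, fell by 0.61 on the log2 scale (SE 0.19, adjusted p = 0.0250), and that of Xirp2, which encodes an actin-binding repeat protein, fell by 0.59 (SE 0.19, adjusted p = 0.0357). Actn2, the alpha-actinin gene of the Z disc in all fibre types, went the other way, from 33.3 ± 3.60 to 53.8 ± 3.20 CPM (log2 fold change 0.69, SE 0.18, adjusted p = 0.00455). The promoter of Myom1, an M-band gene, gave -0.43 (adjusted p = 0.145). The Klhl41 and Xirp2 calls were lost without WT replicate 4 (adjusted p = 0.265 and 0.404), KO replicate 4 (0.0901 and 0.0994), KO replicate 5 (0.183 and 0.233) or KO replicate 7 (0.0990 and 0.137), and the Actn2 call without WT replicate 3 (0.0507) or KO replicate 5 (0.0608). The Xirp2 call was also lost with DESeq2 (adjusted p = 0.0787), limma-voom (0.0512) and total counts (0.0559). The list itself had a median of 0.13 without WT replicate 4 (adjusted p = 0.975) and an adjusted p of 0.184 without KO replicate 7. With the authors' factors the median was 0.04, and camera still passed.

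Calcium handling and T tubule promoters were also lower by camera with its preset correlation (17 genes, median -0.08, adjusted p = 0.00845), but not with an estimated correlation (adjusted p = 0.799) or by fry (adjusted p = 0.834). Of these promoters 0 were higher, 2 were lower and 15 did not pass, with the same counts adjusted over the list alone. Mss51, a muscle gene placed on the list beforehand, fell from 17.1 ± 2.29 to 7.66 ± 2.08 CPM at its promoter (log2 fold change -1.16, SE 0.22, adjusted p = 2.05e-05), and Trdn, which encodes the junctional protein triadin, fell from 33.4 ± 10.4 to 17.2 ± 2.47 CPM (log2 fold change -0.96, SE 0.19, adjusted p = 6.12e-05). Jph2, a junctophilin gene, gave -0.26 (adjusted p = 0.5). The list's call is lost without WT replicate 4 (median 0.08, adjusted p = 0.656) and without KO replicate 7 (adjusted p = 0.180). With the authors' factors the median was 0.11, and camera still passed.

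**Figure D2:**
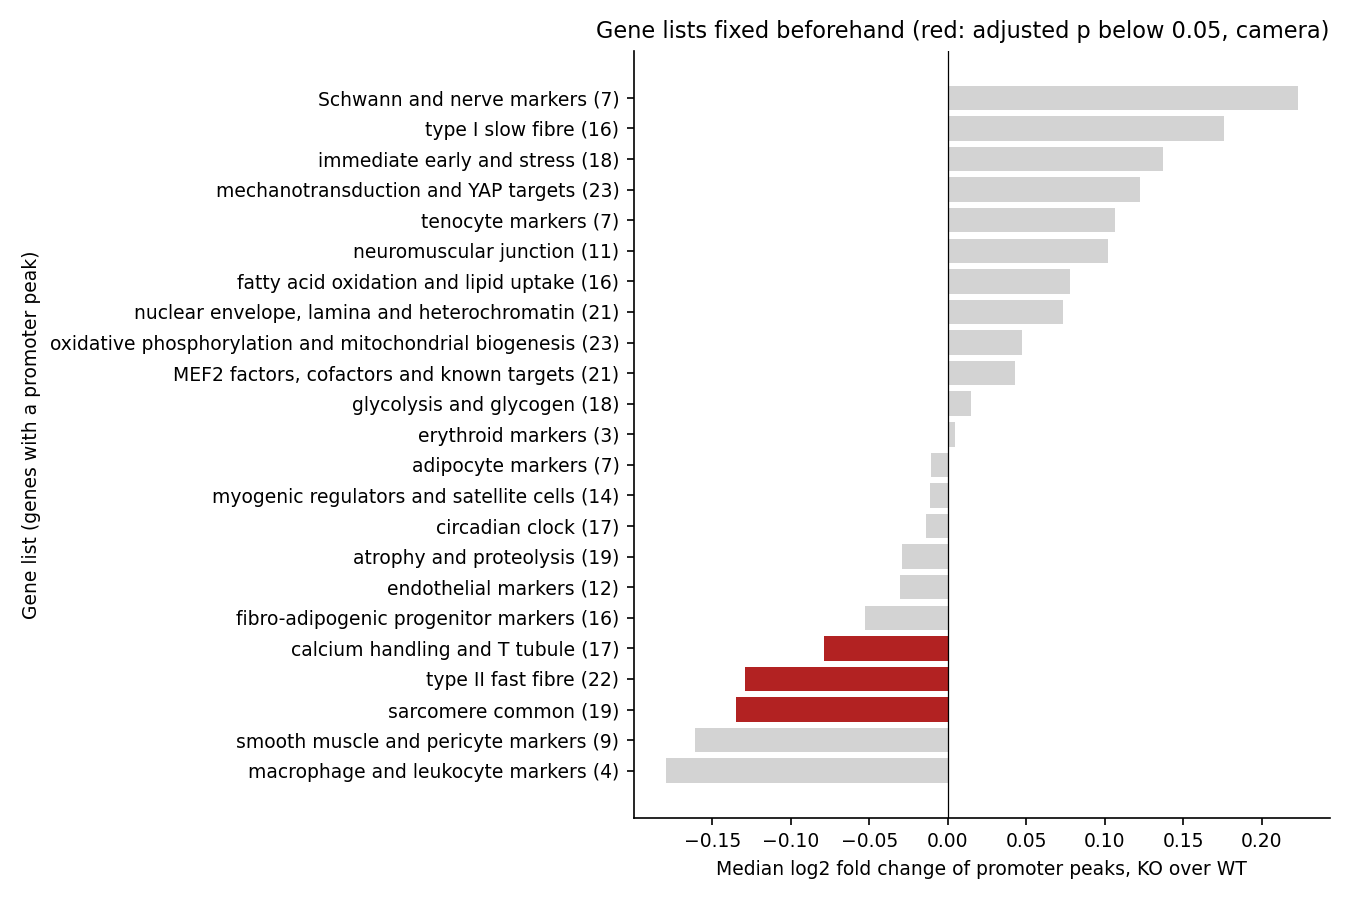
Median log2 fold change of KO over WT at promoter peaks (horizontal axis) for the 23 gene lists, with the number of genes with a promoter peak in parentheses; red bars passed camera at an adjusted p of 0.05 with an inter-gene correlation of 0.01. The 3 red bars, at -0.13, -0.13 and -0.08, are the sarcomere, fast fibre and calcium handling lists. None of them passed with an estimated correlation, and with the authors' factors their medians were 0.04, 0.04 and 0.11.

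The MEF2 genes had no called promoter peak: the log2 fold change was -0.09 at Mef2a (SE 0.18, adjusted p = 0.881), -0.14 at Mef2c (SE 0.26, adjusted p = 0.870) and 0.09 at Mef2d (SE 0.18, adjusted p = 0.878). Over the alternatives the Mef2a value ran from -0.21 to 0.09 and the Mef2c value from -0.29 to 0.09, with both at 0.09 under the authors' factors and none passing. That Mef2c peak (83571963 to 83572580) lies at an annotated start site inside the gene. A peak over the start of its RefSeq span (83502696 to 83504533) gave -0.40 (SE 0.20, adjusted p = 0.282). Other promoter-class peaks of Mef2c gave -0.72 to -0.10, and none passed. Peaks outside the promoters that were annotated to the MEF2 genes passed. Inside the Mef2c span, an intronic peak (83595973 to 83597047) gave -1.35 (SE 0.26, adjusted p = 2.68e-05). Another intronic peak (83637654 to 83639329) gave -1.22 (SE 0.23, adjusted p = 1.37e-05). Both were chosen after their values were seen, and the other lower Mef2c peaks were intergenic. A peak 438937 bases upstream of Mef2c (chromosome 13, 83064583 to 83065611) fell from 15.5 ± 1.59 to 4.33 ± 1.41 CPM (log2 fold change -1.85, SE 0.25, adjusted p = 4.37e-11), and 8 of 43 peaks annotated to Mef2c fell and 0 rose, with 4 lower without WT replicate 4, 4 without KO replicate 4 and 5 without KO replicate 5. The lower Mef2c count was 5 with the authors' factors in edgeR and 3 in the table of the authors. A peak 29983 bases upstream of Mef2a (chromosome 7, 67402129 to 67403552) fell by 1.36 (SE 0.22, adjusted p = 1.75e-07). At Mef2d a weak peak 10982 bases upstream (chromosome 3, 88131254 to 88131526) rose by 1.09 (SE 0.32, adjusted p = 0.0131), a call lost without WT replicate 3 (adjusted p = 0.0634), WT replicate 8 (0.0607), KO replicate 4 (0.0973) or KO replicate 5 (0.0891). Assignment of distal peaks to a gene is by nearness in the deposited annotation. The list of MEF2 factors, cofactors and known targets had a median of 0.04 over 21 promoters (camera adjusted p = 0.508; mean 0.02, test direction down), with 0 promoter peaks called, also when adjusted over the list alone. DESeq2 and limma-voom called 0 as well, and 1 had an unadjusted p under 0.05 in edgeR.

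Chrna1, the alpha subunit gene of the muscle acetylcholine receptor, rose at its promoter, with the smallest p of all promoter peaks in the lists. The peak (ENSMUSG00000027107, chromosome 2, 73579307 to 73580654) rose from 7.90 ± 1.37 to 27.1 ± 3.01 CPM, a fold change of 3.41 (log2 fold change 1.77, SE 0.21, adjusted p = 2.44e-13). Other promoters of the neuromuscular junction list did not pass: 11 genes, 1 higher, 0 lower, 10 not passing, with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.221). The list passed camera with its preset correlation, higher in KO, without WT replicate 4 (median 0.20, adjusted p = 0.0275) and without KO replicate 7 (median 0.15, adjusted p = 0.00567). Over all 61 peaks of these genes, 6 rose and 1 fell, with 3 rising without KO replicate 5, and camera on all peaks passed (adjusted p = 4.04e-04) but not with an estimated correlation (adjusted p = 0.851). In the list of myogenic regulators and satellite cells (14 promoters, median -0.01, mean 0.05, camera direction down, adjusted p = 0.572; 1 higher, 1 lower, also over the list alone), which shares Chrna1, the other called promoter was Myf6, the myogenic factor gene of mature fibres, down from 59.3 ± 7.97 to 30.8 ± 4.32 CPM (log2 fold change -0.95, SE 0.18, adjusted p = 2.01e-05).

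**Figure D3:**
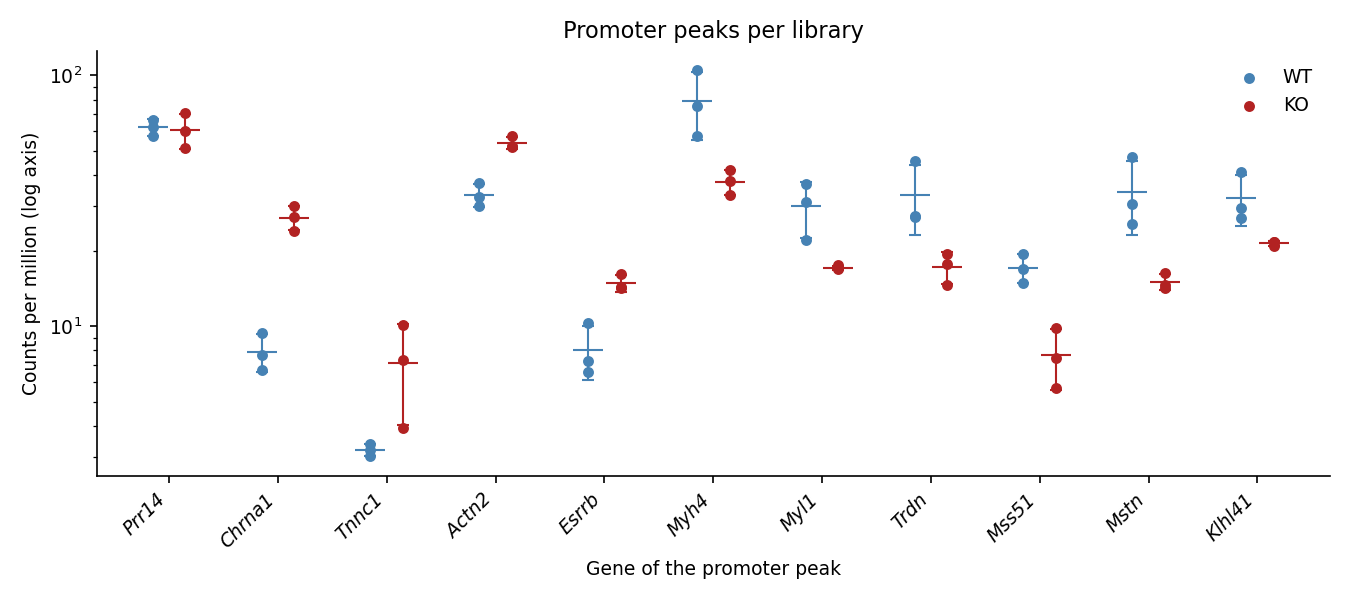
CPM on a log axis at the promoter peak of each named gene, with 3 WT (blue) and 3 KO (red) libraries as points and the mean and SD as bars. Chrna1 lies between 7.90 (WT mean) and 27.1 (KO mean), Prr14 is at 62.0 and 60.5, and Mstn falls from 34.4 to 15.02.

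Metabolic, proteolysis and mechanotransduction lists did not pass as groups, and single promoters did. Mstn, which encodes the muscle growth inhibitor myostatin, fell from 34.4 ± 11.2 to 15.02 ± 1.12 CPM (log2 fold change -1.20, SE 0.20, adjusted p = 2.27e-07), the only called promoter of 19 in the atrophy and proteolysis list (median -0.03, camera adjusted p = 0.221, and 0.0131 without WT replicate 8). Esrrb, an oestrogen-related receptor gene, rose from 8.04 ± 1.96 to 14.9 ± 1.15 CPM (log2 fold change 0.90, SE 0.23, adjusted p = 0.00286), the only called promoter of 23 in the oxidative phosphorylation list (median 0.05, camera adjusted p = 0.440; over all 129 peaks, camera adjusted p = 0.00482, and 0.851 with an estimated correlation). Of those 129 peaks 12 rose and 2 fell, with 5 rising without WT replicate 3 and 6 without KO replicate 4. Tead4, a transcriptional partner of YAP, rose by 0.68 (SE 0.22, adjusted p = 0.0345), the only called promoter of 23 in the mechanotransduction list (median 0.12, mean 0.06, camera direction down, adjusted p = 0.867). The Tead4 call was lost with DESeq2 (adjusted p = 0.120) and without WT replicate 4 (0.0587), WT replicate 8 (0.249), KO replicate 5 (0.0826) or KO replicate 7 (0.339). Npas2, a clock gene, rose by 0.88 (SE 0.21, adjusted p = 0.00157), 1 of 17 in the circadian list (median -0.01, mean 0.07, camera direction up, adjusted p = 0.967). These 4 single calls were also the only calls adjusted over each list alone.

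No promoter was called in the remaining muscle, metabolism and stress lists. The glycolysis and glycogen list had a median of 0.01 over 18 promoters (mean -0.04, camera direction down, adjusted p = 0.222, and 0.0131 without WT replicate 8), fatty acid oxidation 0.08 over 16 (0.336), the nuclear envelope and heterochromatin list 0.07 over 21 (0.801) and immediate early and stress genes 0.14 over 18 (0.400). DESeq2 and limma-voom called 0 promoters in these 4 lists too, and edgeR gave an unadjusted p under 0.05 for 2, 5, 1 and 1 of them.

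No list of markers of other cell types passed camera. Endothelial markers had a median of -0.03 over 12 promoters (camera adjusted p = 0.440), where Cldn5, a tight junction gene, rose by 0.71 (SE 0.19, adjusted p = 0.00594), lost without WT replicate 4 (0.0627) or KO replicate 5 (0.313). Adipocyte markers had -0.01 over 7 promoters (0.221), where Car3, which muscle also expresses, fell by 0.88 (SE 0.20, adjusted p = 5.67e-04). Smooth muscle and pericyte markers had -0.16 over 9 (0.221) with 1 lower when adjusted over the list alone and 1 called by limma-voom, fibro-adipogenic progenitors -0.05 over 16 (0.222), tenocytes 0.11 over 7 (0.446), macrophages and leukocytes -0.18 over 4 (0.221), Schwann and nerve markers 0.22 over 7 (0.221) and erythroid markers 0.00 over 3 (mean -0.09, camera direction down, adjusted p = 0.440). Leaving out WT replicate 4 made the fibro-adipogenic list pass camera with its preset correlation, lower in KO (median -0.15, adjusted p = 0.00400). An estimated correlation was not computed for that setting.

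Across the genome, 5177 peaks (7.01%) changed, 2049 higher and 3128 lower in KO, and 4883 of them had all 3 KO libraries on one side of all 3 WT libraries, as did 20.3% of all tested peaks, where chance gives 10%. Among the called peaks named by the rule, the groups overlapped at Tead4 only, but the rule itself required separate groups for the largest changes. The higher peaks had a median log2 fold change of 0.93 and the lower ones of -0.99. The share that was higher, 39.6%, depends on the scaling: the authors' deposited table has 2201 peaks past its adjusted p, 1622 higher and 579 lower (73.7% higher), with a median log2 fold change over all peaks of 0.19 against -0.01 here. With the authors' factors in edgeR, 12 named calls did not pass, in the same direction: Myh4 (promoter), Myh2, Myl1, Klhl41, Xirp2, Myf6, Trdn, Tead4, Car3, Smtnl1, Actn2 and Cldn5. Of the authors' 2201 peaks, 2124 were also called by edgeR in the same direction. Leaving out WT replicate 4 raised the share to 61.1%, with 1409 lower, and leaving out KO replicate 7 gave 49.8%, with 2082 lower. Without KO replicate 5 there were 2470 calls, 959 higher and 1511 lower, and 1279 or 1209 peaks were higher without WT replicate 3 or KO replicate 4.

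The largest gains lay within the Esr1 gene (ENSMUSG00000019768), which encodes oestrogen receptor alpha. An exonic peak of 270 bases (chromosome 10, 4856925 to 4857194) rose from 1.19 ± 0.371 to 33.1 ± 15.3 CPM, a log2 fold change of 4.76 (SE 0.27, adjusted p = 2.45e-62). A peak of 245 bases (5001186 to 5001430) rose from 1.53 ± 0.455 to 31.8 ± 15.6 CPM (log2 fold change 4.39, SE 0.27, adjusted p = 3.57e-56). Its deposited class is 3' UTR and its annotated gene is Syne1. It lies inside the RefSeq span of Esr1 (4611989 to 5005633) and outside that of Syne1 (5020192 to 5550692). The other largest gains were an intronic peak annotated to Rasd1 (2.63) and one in Tmem163 (2.53), followed by peaks near or in Lin9, Hephl1, Lhfpl2, Samd13, Cfap54 and Clmn with log2 fold changes from 2.36 to 2.19. WT levels at these gains were low, from 0.570 CPM at Rasd1 to 6.28 CPM at Clmn, so the sizes at the weakest are imprecise. Large losses were peaks annotated to Spaca7 (-3.17), H2al1n (-3.05), Enox2 (-2.81), Pmp2 (-2.79), Kirrel3 (-2.68), Atp8a2 (-2.65), Mylk4 (-2.63) and Tsga8 (-2.60). Those of H2al1n, Enox2, Pmp2 and Kirrel3 were intergenic, 18309, 16195, 9902 and 71793 bases from the annotated start site. The Tsga8 peak, of class intron, lay 92212 bases upstream of the Tsga8 start site. The gene is thus a label by nearness. KO levels at these losses ran from 0.284 CPM at Pmp2 to 4.27 CPM at Kirrel3, so the sizes at the weakest are imprecise. The Kirrel3 peak (chromosome 9, 34413350 to 34414851) was the strongest of these, falling from 27.2 ± 6.41 to 4.27 ± 0.575 CPM (adjusted p = 4.64e-27). The Pmp2 call was lost without WT replicate 8 (adjusted p = 0.214), KO replicate 5 (0.0506) or KO replicate 7 (0.106), and the Tsga8 call without WT replicate 4 (0.112) or KO replicate 4 (0.0736).

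**Figure D4:**
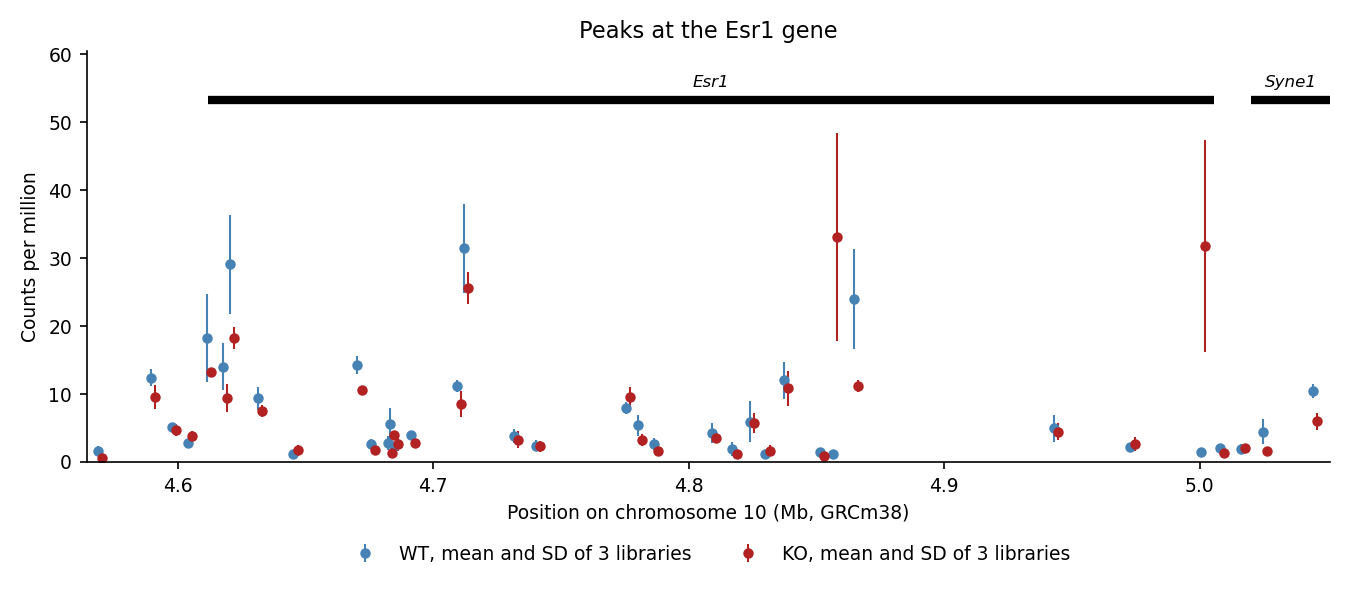
CPM (vertical axis) for each tested peak at the Esr1 gene by position on chromosome 10 in Mb; points are means and bars SDs of 3 WT (blue) and 3 KO (red) libraries. A pair of narrow peaks at 33.1 and 31.8 CPM in KO stands above WT values of 1.19 and 1.53, and no other peak within the gene span was called higher.

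Changed peaks lay outside promoters more often than unchanged ones. Promoters made up 13.4% of higher peaks (odds ratio 0.476, Fisher's exact test, adjusted p = 4.92e-34) and 8.31% of lower peaks (odds ratio 0.278, adjusted p = 1.55e-117), against 24.6% of unchanged peaks. Introns were over-represented among higher (odds ratio 1.24) and lower (1.45) peaks, as were intergenic regions (1.18 and 1.29) and exons (1.42 and 1.29). Lower peaks lay at a median of 32468.5 bases from the annotated start site, higher peaks at 17453 and unchanged peaks at 16651. Peaks are not independent replicates, so these tests describe the called peaks. Across peaks, Spearman's rho of the log2 fold change was 0.05 with peak width and 0.11 with mean signal.

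By chromosome, 9 of 22 differed from the rest in the share of changed peaks (Fisher's exact test). Chromosome 3 had 9.92% changed, 77 higher and 289 lower (odds ratio 1.496, adjusted p = 3.53e-10), and the X had 13 higher and 90 lower of 1083 (odds ratio 1.40, adjusted p = 0.0184). On the Y, 6 of 23 peaks fell and 0 rose (odds ratio 4.69, adjusted p = 0.0184). All 6 lay between 90737869 and 90813886, and the 12 peaks before 90 Mb had 0 calls, so the Y result rests on 1 stretch. Neighbouring peaks are not independent replicates, so the chromosome tests describe the called peaks. Chromosomes 10, 13 and 16 also had more changed peaks and chromosomes 2, 4 and 11 fewer. The number of such chromosomes was 3 without WT replicate 4 and 4 without WT replicate 8. It was 3 with total counts, 4 with loess offsets, 2 without X, Y and mitochondrial peaks, and 1 in the authors' table. Y chromosome reads made up 0.0474 ± 0.00997% of counts in WT and 0.0318 ± 0.00392% in KO, and mitochondrial reads 8.63 ± 2.89% and 6.53 ± 1.604% (exact permutation p = 0.1 and 0.4, n = 3 each).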

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

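The alternatives using the authors' factors and the totals outside mitochondrial peaks were chosen after seeing the data. Other tools, scalings, filters and thresholds left most called peaks lower (38.8% to 48.3% higher over 11 settings), promoters under-represented in both directions (odds ratios 0.308 to 0.648 and 0.192 to 0.346 over 23 settings) and the Prr14 peak unchanged (log2 fold change -0.14 to 0.17). The share higher turned with the authors' adjusted p (73.7%; 2201 peaks, 579 lower), their raw p (72.1%; 9794 peaks, 7057 higher), their factors in edgeR (68.3%; 2372 peaks, 752 lower) and in DESeq2 (73.3%; 2254 peaks, 602 lower). With their factors and without WT replicate 8, 2867 peaks changed, 1217 higher and 1650 lower (42.4% higher), and the median shift fell from 0.19 to 0.07. Leaving out 1 library at a time gave 2470 to 5359 peaks, 959 to 2248 higher, 1409 to 3111 lower, 34.0% to 61.1% higher, 3 to 10 chromosomes and 2 to 5 lists. Chromosomes with another share of changed peaks numbered 3 with total counts, 4 with loess offsets, 2 without X, Y and mitochondrial peaks, 1 and 0 with the authors' adjusted and raw p, and 3 and 1 with their factors in edgeR and DESeq2. Gene lists past camera numbered 5 with loess offsets, 5 with the authors' factors without WT replicate 8, 5 over all peaks and 0 with an estimated correlation; without WT replicate 4 the medians of all 3 passing lists turned positive (fast fibre 0.06, calcium handling 0.08, sarcomere 0.13, the last within -0.25 to 0.13 over the left-out libraries). The cause was not tested for chromosomes, and for lists only as far as WT replicate 4 alone. Of the 51 named peaks beside Prr14, 0 called ones turned in any setting, and the uncalled promoter peaks of Mef2a and Mef2c changed sign in some (to 0.09 with the authors' factors); calls lost were 2 with DESeq2, 12 with the authors' factors in edgeR and 3 to 7 without a library. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Motif tests and GC offsets were not run for lack of a genome sequence.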

Other observations

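The tests weighed in this part, those on other splits of the libraries included, were written down after the results were seen. Several genes changed over many peaks, and those named here were chosen after their counts were seen. In KO, 12 of 23 peaks fell at Ppp1r3a, a glycogen-targeting phosphatase subunit gene, and 8 of 13 at Phka1, a phosphorylase kinase subunit gene, with 0 higher. Their median log2 fold changes were -0.86 and -1.11. Without WT replicate 4 the lower counts were 5 and 0, without KO replicate 5 they were 5 and 4, and Phka1 had 2 without KO replicate 7. With the authors' factors in edgeR they were 5 and 1.

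In the other direction, all 4 tested peaks rose at Ldhb, the lactate dehydrogenase gene of oxidative tissue (median 1.18), 7 of 13 at Actn2 (0.69) and 8 of 26 at Esrrg, an oestrogen-related receptor gene (0.40), with 0 lower. At Usp29, 9 of 12 rose (1.07). With the authors' factors in edgeR the counts were 4 at Ldhb, 3 at Actn2, 6 at Esrrg and 10 at Usp29. Without KO replicate 4, 3 Actn2 peaks and 4 Esrrg peaks rose; without WT replicate 3, 3 Actn2 and 3 Esrrg peaks, with 3 at Ldhb without either of these libraries; without KO replicate 5, 4 Actn2 peaks and 6 Usp29 peaks. Of 1040 genes with at least 2 called peaks, 830 had all of them in one direction.

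The 2 Esr1 peaks invite a question about extra DNA. If the KO animals carried additional copies of Esr1 exon sequence, for example in a transgene with a hormone-binding domain of the receptor, gains would be limited to fragments of it, and 0 of the 26 other tested peaks within the gene were called higher, which restates the pattern that prompted the idea and lends it no support. Opening of the whole locus is argued against, since those 26 peaks had a median log2 fold change of -0.36 and 2 of them fell. The bootstrap 95% interval of that median, -0.57 to -0.16, came from resampling these peaks and holds no spread between libraries. In every KO library both peaks were at or above 15.04 CPM, and in every WT library at or below 1.84. Extra copies are a hypothesis that is not excluded, and the reads themselves were not available to test it. The deposited annotation gives one of the pair the class exon with Esr1 and the other the class 3' UTR with Syne1. Both lie inside the RefSeq span of Esr1 and outside that of Syne1 (5020192 to 5550692). A local gain at these elements stays open, untested.

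The direction of the genome-wide split differs between the authors' table and edgeR with TMM. The authors' factors alone produce the turn, with 68.3% of calls higher when they are used in edgeR. WT replicate 8, the library with the fewest counts, may carry much of it, since without it the share under these factors was 42.4%, while leaving out any other library gave 53.8% to 89.99%, the last without WT replicate 4. Greater accessibility in KO overall cannot be told apart from library differences, because no spike-in is named in the sources used here and nuclear counts per authors' factor did not separate the groups (exact permutation p = 0.5).

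The fast fibre, sarcomere and calcium handling lists were lower by camera with its preset correlation only, with 0 of them past with an estimated correlation or by fry, and most of their promoters were not called. A lower share of myofibre nuclei as the whole cause was weighed by called gains at myofibre genes. In the slow, fast, sarcomere, neuromuscular junction and calcium handling lists, 20.8% of 173 calls were higher, beside 39.6% of all calls. These were 36 peaks at 19 of 46 genes (95% interval 10.3% to 37.3% from resampling genes, since peaks of a gene are not independent). Peaks were assigned by nearness at any distance and can belong to other cell types, so this share cannot decide it. WT replicate 4 alone may account for the list calls, as 0 of the 3 lists stayed past camera without it. For the sarcomere and calcium handling lists the loss is not particular to it, as both calls were also lost without KO replicate 7 (adjusted p = 0.184 and 0.180). The fast fibre list lost its camera call without WT replicate 4 (adjusted p = 0.233) and without no other library. Without WT replicate 4, 34 of the 47 called lower peaks of the fast fibre list (72.3%) stayed called lower. WT replicate 4 alone is argued against for those of Mylk4 (20 of 21 stayed) and Myh4 (6 of 7). Other genes of the list were mixed, with 4 of 7 at Myl1, 1 of 1 at Myh2, 1 of 3 at Eya1 and 0 of 3 at Tpm1. Peaks of a gene are not independent, so for the list as a whole it stays open. Over all tested peaks of that list, the median went from -0.17 to -0.05 (95% interval -0.46 to 0.11) without WT replicate 4. WT replicate 4 alone also stays open for the called lower peaks of the sarcomere list (24.4% stayed) and the calcium handling list (45.2%), where leaving out KO replicate 5 left 17.1% and 41.9%. Of all lower calls, 42.4% stayed without WT replicate 4. The median log2 fold changes of the called peaks went from -0.79 to -0.57 and from -1.07 to -0.83, on peaks selected by calls that used every library. Over all tested peaks they went from -0.28 to -0.11 (-0.24 to 0.11) and from -0.30 to -0.11 (-0.48 to 0.10), so the values do not decide it. A shift between fibre types and sampling of a slower part of the muscle cannot be told apart: 2 slow fibre promoter peaks were called higher, each lost without 1 library, while over all peaks of these genes 5 rose and 17 fell, and the sampled part of the muscle is not given.

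In 10 splits of the 6 libraries into 3 and 3, 1 gave as many called peaks, the real one (5177); the highest of the other splits was 0 in edgeR, with 1164 to 5138 peaks at an unadjusted p under 0.05 against 12542. The splits are too few for a share under 0.05.

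On the Y chromosome, the 6 lower peaks lay among the 11 from 90 Mb on (median log2 fold change -1.03), next to 12 earlier peaks with a median of -0.22 and 0 calls. A Mid1 intronic peak on the X (169993739 to 169994961), chosen after its value was seen, fell by 1.44.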
